A study of Mus musculus with 6 samples.

How the data were processed

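RNA was extracted with a column kit (Qiagen RNeasy Plus mini) from 6 samples of mouse AE9a leukemia cells with loxP-flanked Id1 alleles and CreER, and libraries were made by the standard Illumina protocols per the labels. The labels place 2 samples in each of 3 groups: control, CBD and 4-OHT. They do not say whether the samples of a group were separate cultures, name no vehicle for the control, and list no 4-OHT arm without loxP sites. Per the labels, the authors aligned reads with Bowtie 0.12.2 to mm9 and compared groups with Cuffdiff, whose version, settings and gene annotation are not given in the sources used here.

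Each of the 2 tables holds FPKM values (fragments scaled to transcript length and to the mapped total) that the authors computed, 1 per group, so 4 FPKM columns in all. The deposited p-value and q-value columns hold the result of the authors' Cuffdiff test. The deposited log2 column gives the treated over the control FPKM. It was used only as a check. The deposited q was recomputed from the deposited p by the Benjamini-Hochberg method over genes with status OK and differed by at most 1.52e-06. The deposited log2 fold differed from the FPKM ratio by over 0.01 in 203 genes of the CBD table and 18 of the 4-OHT table, all with status FAIL. Status OK was given to 13751 genes with CBD and 11232 with 4-OHT, and these are the genes called tested. The other genes were marked as not tested (7822 and 10541), with low data (88 and 88), failed (211 and 20) or, in the CBD table, with too many fragments (9). Some genes outside the test, such as Eef1a1 in the CBD table, are listed at 0, which is a failed estimate and no measurement. Among tested genes, 967 with CBD and 54 with 4-OHT are listed at 0 in 1 column, and the text prints no fold for a single one of those. Their folds, computed with the pseudocount given below, do enter the list medians, the random lists, the 2-fold counts, the correlation and the plotted points. Several symbols are named in 70 entries of each and no symbol is repeated.

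Read counts, library sizes and values per library are not used here, because the tables give 1 value per group. The depth is therefore unknown, and no replicate spread, confidence interval or detection limit was computed for an FPKM value. The rule for this case, like the comparisons, the gene lists, the rule for named genes and the first set of alternative settings, was set before the data were examined: a gene counts as changed when the authors' deposited q is under 0.05, and its log2 fold is that of treated over control with a pseudocount of 0.1 FPKM added to each. No test for changed genes was added, and the only interval given, in the closing section, is an exact binomial interval for a share of genes, which are not independent. Deposited q values of 0 are given as listed as 0.

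For each of 32 fixed gene lists, members that rose and fell were counted over all tested genes, and again after Benjamini-Hochberg adjustment of the deposited p over the list alone. The median log2 fold of tested members was placed among those of 10000 random lists of the same size, drawn without replacement from tested genes and matched on mean FPKM in 10 bins. A list lies outside when its median is outside the central 95%. In each comparison 1.6 lists would lie there by chance if the genes of a list moved independently. These percentiles describe the lists and are no test, since genes of a list move together. A further 12 lists, of neurons, oligodendrocytes, astrocytes, microglia, 7 other tissues and Y-linked genes, were written after the data were seen, and part of the neural members had been seen high with CBD by then.

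Genes were named by rule: Id1, Id2, Id3 and Id4, the 8 highest and 8 lowest log2 folds among changed genes with a mean of at least 1 FPKM, up to 3 changed members with the largest fold from each list that lay outside or had at least 25% of its members changed, and the 5 genes with the largest change in both comparisons, in the same and in opposite directions. Predicted genes and small nucleolar and micro RNAs were passed over. Y-linked genes, further neural genes and the genes that differ most between the control columns were chosen after their values were seen. The overlap of the comparisons was set against the product of the list sizes over the genes tested in both.

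Transcript lengths are the longest annotated transcript of each gene in the GENCODE vM21 annotation, which covers 97.9% of the genes by symbol. It belongs to a later genome build than mm9 and was used for lengths and symbols alone. The length trend was the median log2 fold in 20 bins of length over genes at 10 FPKM or more in both control columns, interpolated between bins, and adjusted folds are the folds minus that trend. Gene positions are those of the tables, with 1 added to each start, because end minus start equals the RefSeq length in 6275 of 19307 genes and the length minus 1 in 432.

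The alternatives were a q threshold of 0.01, a minimum of 2-fold, a minimum of 1 FPKM with and without recomputed q, folds centred on their median, pseudocounts of 0.01 and 1, random lists matched in 20 bins or unmatched, and other expression limits for the correlation. Alternatives chosen after the data were seen were a minimum of 1 FPKM in both control columns, the control column of the other table, removal of the length trend, and the pseudocounts for named genes. The Benjamini-Hochberg step alone was tested on simulated p-values, with 200 small ones planted among uniform ones. Recovery was 100%, with 3.85% false calls at the number of genes of the CBD table and 7.41% at that of the 4-OHT table. No FPKM values or replicates were simulated for this step, so the authors' deposited calls were not checked by it. Simulated lists of 25 genes lay outside in 5% of cases with no shift, and with a log2 shift of 0.5 in 45% for CBD and 100% for 4-OHT. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.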

Results

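RNA-seq was carried out on mouse leukemia cells driven by AE9a, a truncated form of the AML1-ETO fusion protein. The cells carry loxP-flanked Id1 alleles and CreER, a Cre recombinase that tamoxifen metabolites switch on. The 6 samples form 3 groups of 2: control cells, cells given CBD at 15 µM for 16 h, and cells given 4-hydroxytamoxifen (4-OHT) at 0.1 µM for 48 h. The design text calls CBD an inhibitor of Id1 and does not spell the abbreviation out. Each of the 2 deposited tables lists 21881 genes with 1 FPKM value for control, 1 for the treated group, and the authors' p and q. The values of single libraries and their depths are not in these tables, so no SD, n or interval can be set beside a value, and "rose" or "fell" below always means a q under 0.05 in the authors' deposited table. The tables were made separately and hold different control columns. The description of one control sample names the CBD comparison and that of the other names the 4-OHT comparison, and how many libraries stand behind a control column is not stated.

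Id1, a helix-loop-helix protein that lacks a DNA-binding domain and keeps E proteins off DNA, is the gene both treatments are aimed at. With 4-OHT, Id1 fell from 15.4 to 0.741 FPKM, a log2 fold of −4.21, with a q listed as 0 in the authors' deposited table. The gene lies on chromosome 2 from 152562010 to 152563146 in mm9. Its FPKM covers the whole gene, and the labels do not say which exons are flanked by loxP sites, so reads from a part that is kept would count. With CBD, Id1 stood at 34.2 FPKM in the control and 11.95 in the treated column, a log2 fold of −1.51 that did not pass the test (p = 0.0458 and q = 0.133 in the authors' deposited table). Set against the control column of the separately made 4-OHT table, the CBD value differs by a log2 fold of −0.37, which was not tested.

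Id2, another member of this family, rose with CBD from 4.28 to 25.04 FPKM (q = 9.48e-08 in the authors' deposited table). Against the other table's control column, at 10.1 FPKM, its log2 fold with CBD is 1.30 in place of 2.52. With 4-OHT, Id2 fell from 10.1 to 7.81 FPKM (q = 0.00555 in the authors' deposited table), although 7.81 is above the 4.28 FPKM of the other table's control column. Id3 passed neither test: it stood at 5.21 and 4.87 FPKM in the CBD table and at 2.45 and 1.72 FPKM in the 4-OHT table. Id4 is listed at 0 in the other 3 columns and at 4.05 FPKM with CBD, with a q of 0.138 in the authors' deposited table.

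**Figure D1:**
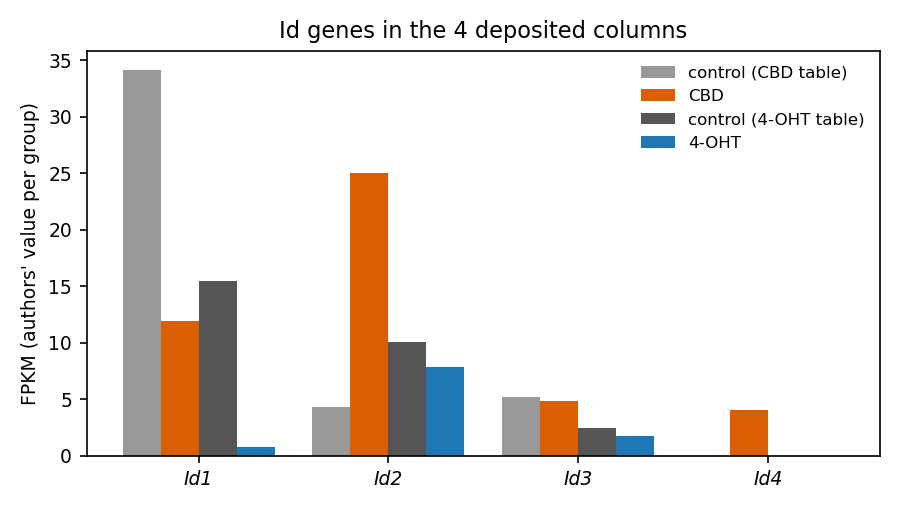
Bars give the authors' FPKM of Id1, Id2, Id3 and Id4 in the 4 deposited columns, with no error because each group has 1 value. Id1 is lower in each treated column than in its own control, reaching 0.741 FPKM with 4-OHT, and Id2 is at 25.04 FPKM with CBD.

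The CBD comparison asks what the compound changed within 16 h. Genes of mitosis fell: of 29 tested G2/M genes, 28 fell and none rose, and 28 also fell when adjusted over the list alone. Mki67, which encodes the Ki-67 proliferation antigen, fell from 58.3 to 1.84 FPKM. The mitotic kinesin gene Cenpe fell from 9.10 to 0.366 FPKM and the kinetochore gene Cenpf from 10.6 to 0.594. Among 28 tested G1/S and DNA replication genes, 19 fell and none rose (24 and 0 adjusted over the list alone). Examples are Pole, the catalytic subunit of DNA polymerase epsilon, from 29.5 to 5.72 FPKM, the chromatin assembly factor gene Chaf1a from 40.9 to 9.86, and the replication licensing gene Cdt1 from 100.3 to 27.8. The median log2 fold was −1.66 for the G2/M list and −1.14 for the G1/S list, each below all 10000 random lists of the same size and expression. E2f7, a repressor of E2F target genes, fell from 4.15 to 0.477 FPKM. The other genes with the lowest folds were the junction protein gene Cgnl1, from 6.28 to 0.724 FPKM, the centrosome gene Cep110, from 6.71 to 0.822, and the signalling scaffold gene Ccdc88c, from 13.1 to 1.69. Against the other control column, at 1.54 FPKM, the log2 fold of Cgnl1 is −0.99 in place of −2.95.

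MYC target and ribosome biogenesis genes were lower too, with 13 of 28 tested genes falling and none rising (14 and 0 adjusted over the list alone). Polr1a, the largest subunit of RNA polymerase I, fell from 40.0 to 14.0 FPKM, the nucleolar helicase gene Ddx21 from 122.7 to 52.98, and nucleolin (Ncl) from 191 to 84.8. The cytosolic ribosomal protein genes did not share this direction: none of 34 passed the test, and their median log2 fold was 0.59. Fold changes in the CBD column declined with transcript length (Spearman rho = −0.42 across 5861 genes, which are not independent replicates). Mki67, Cenpe and Cenpf have annotated transcripts of up to 10061, 7910 and 11130 bp, and their log2 folds of −4.91, −4.30 and −3.94 became −4.17, −3.67 and −3.20 once that trend was removed. The log2 folds of Polr1a, Ddx21 and Ncl went from −1.51, −1.21 and −1.17 to −0.76, −0.96 and −0.48. These adjusted folds rest on the longest annotated transcripts, of 9216, 4722 and 8202 bp. Which transcripts the cells express was not examined, so the adjustment is too large where a shorter one prevails. With the trend removed, the G2/M and G1/S medians were −1.72 and −1.18, and the ribosomal protein median of 0.28 no longer lay outside the central 95% of random lists.

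Lysosome and autophagy genes rose with CBD: 17 of 28 tested genes rose and 1 fell, with the same counts adjusted over the list alone. Lamp2, a lysosomal membrane protein, rose from 44.7 to 158 FPKM, the beta-hexosaminidase subunit gene Hexa from 7.49 to 29.2, and cathepsin L (Ctsl) from 1.17 to 5.13. Of 27 NRF2 and oxidative stress genes, 12 rose and none fell (14 and 0 adjusted over the list alone). Hmox1, which encodes the haem-degrading enzyme haem oxygenase 1, rose from 32.8 to 205 FPKM, sulfiredoxin (Srxn1) from 12.1 to 67.7, and Osgin1 from 0.392 to 2.27. Of 25 endoplasmic reticulum chaperone genes, 11 rose and none fell (12 and 0 adjusted over the list alone), among them the disulfide isomerase genes Pdia6, from 65.5 to 146 FPKM, and Pdia4, from 32.3 to 67.8, and the co-chaperone gene Dnajb9, from 17.6 to 36.6. Against the other control column the log2 folds of Pdia6 and Pdia4 are 0.47 and 0.48 in place of 1.15 and 1.07. The medians of these 3 lists, at log2 folds of 0.97, 0.84 and 0.70, lay above the central 95% of random lists. The autophagy receptor gene Sqstm1 rose from 236 to 805 FPKM. In the same CBD column 49 of 55 tested neural markers and all 3 tested Y-linked genes rose too. Among members at 1 FPKM or more in both control columns, 16 of 27 lysosome, 11 of 24 NRF2 and 11 of 24 chaperone genes rose.

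Of 30 tested interferon response genes, 15 rose with CBD and none fell (16 and 0 adjusted over the list alone). Rsad2, the antiviral protein viperin, rose from 0.167 to 2.92 FPKM, Rtp4 from 0.0731 to 1.85, and the guanylate-binding protein gene Gbp2 from 0.544 to 4.67. Only 13 of the 30 are at 1 FPKM or more in both control columns, and 6 of those rose. The list's median log2 fold of 1.26 lay at the 98.1 percentile of random lists and at the 95.1 percentile when only members at 1 FPKM or more in a group were kept, which is inside the central 95%, and at the 95.6 percentile, also inside, with the length trend removed. In the metallothionein and metal transport list Tfrc, the transferrin receptor, fell from 122.7 to 25.3 FPKM, while the iron exporter gene Slc40a1 rose from 5.56 to 23.7 and the metallothionein gene Mt3 from 14.3 to 52.0. The other table's control column holds 22.6 FPKM of Slc40a1, against which its log2 fold with CBD is 0.065.

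Of 18 tested mast cell and basophil genes, 5 rose and 1 fell with CBD (6 and 1 adjusted over the list alone). The mast cell carboxypeptidase gene Cpa3 rose from 71.9 to 658 FPKM, the IgE receptor chain gene Fcer1a from 52.4 to 342, and the basophil protease gene Mcpt8 from 1.85 to 30.8. The list median of 0.80 stayed within the central 95% of random lists. The other table's control column holds 148 FPKM of Cpa3 and 3.80 of Mcpt8, so both rises are smaller against it. Against that column the median of 16 list members at 1 FPKM or more in either control column was 1.44. Of 19 erythroid genes, 4 rose and 5 fell (4 and 8 adjusted over the list alone), and their median log2 fold of −0.59 lay below all 10000 random lists. Ank1, the red cell ankyrin gene, fell from 21.9 to 3.82 FPKM, while alpha globin Hba-a2 rose from 34.9 to 246, a value that is uncertain because near-identical alpha globin copies share reads. Cdkn2b, an inhibitor of CDK4 and CDK6, rose from 4.54 to 34.6 FPKM, and Gzmb, the protease granzyme B, from 13.04 to 87.2. Egr1, an immediate early transcription factor, fell from 57.6 to 5.28 FPKM, although 5.28 is above the 2.26 FPKM of the other table's control column.

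Among the genes with the highest folds after CBD were transcripts best known from the nervous system. Snap25, a synaptic vesicle fusion protein of neurons, rose from 0.0697 to 36.7 FPKM, Ttr, the transthyretin of choroid plexus and liver, from 0.0986 to 68.7, and Pcp4, named for Purkinje cells, from 0.0576 to 44.4. Ldhb rose from 0.0693 to 65.3 FPKM and the sodium pump subunit gene Atp1b1 from 0.0451 to 30.7. In 3 lists of neuron, oligodendrocyte and astrocyte genes, chosen after these values were seen, 49 of 55 tested genes rose and none fell, and their median was 9.53 FPKM with CBD against 0.0354 in its control. Y-linked transcripts moved with them: the summed FPKM of Ddx3y, Eif2s3y, Kdm5d and Uty was 1.97 with CBD and 0.0393 in its control. None of these Y-linked genes reached 1 FPKM with CBD. The median log2 fold of the 3 tested, 2.60, lay at the 79.1 percentile of random lists, inside the central 95%. The remaining highest folds were small structural RNAs, namely the U1 RNA gene Rnu1b2, the RNase P RNA gene Rpph1 and the U12 RNA gene Rnu12. In that class 16 of 92 tested genes rose and none fell, a share of rises close to that of all tested genes (2533 of 13751). The median log2 fold of the tested genes of the class was nevertheless 1.98 with CBD, and 0.63 with 4-OHT.

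Some members of the lists of other blood and stromal cells rose beside those neural genes. Of 17 tested monocyte and macrophage genes 7 rose (7 adjusted over the list alone), including the complement gene C1qa, from 0.0284 to 5.18 FPKM, cathepsin S (Ctss), from 0.0219 to 4.35, and the CSF1 receptor gene Csf1r, from 0.0102 to 2.16. Of 16 stromal and endothelial genes 7 rose (8 adjusted over the list alone), led by Thy1, a surface protein of neurons, T cells and stromal cells, from 0.0654 to 14.3 FPKM, and the matrix protein gene Sparc, from 1.60 to 18.5. The same Thy1 leads the B, T and natural killer cell list, in which 5 of 10 rose (5 adjusted over the list alone). The medians of the monocyte, stromal and lymphoid lists lay within the central 95% of random lists. Apoe, an apolipoprotein of macrophages and astrocytes in the LXR list, rose from 2.85 to 80.3 FPKM. C1qa and Csf1r are also in the microglia list, written after the data were seen, of which 4 of 12 rose. Its median log2 fold of 3.25 lay at the 99.8 percentile of random lists, outside the central 95%. Thy1 is also in the neuron list. The rises of C1qa, Csf1r and Thy1 therefore cannot be told apart from the neural signal.

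Across all genes, 3598 of 13751 tested genes differed with CBD, 2533 higher and 1065 lower, and 2632 of them by at least 2-fold. Of the 2533 genes that rose, 1496 stood under 1 FPKM in the control. Among genes at 1 FPKM or more in both control columns, a limit set after the data were seen, 991 rose and 1053 fell, so the share of higher calls went from 70.4% to 48.5%. The median log2 fold of all tested genes at 1 FPKM or more in a group was 0.19 with CBD and 0.04 with 4-OHT, and list medians are to be read against it.

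**Figure D2:**
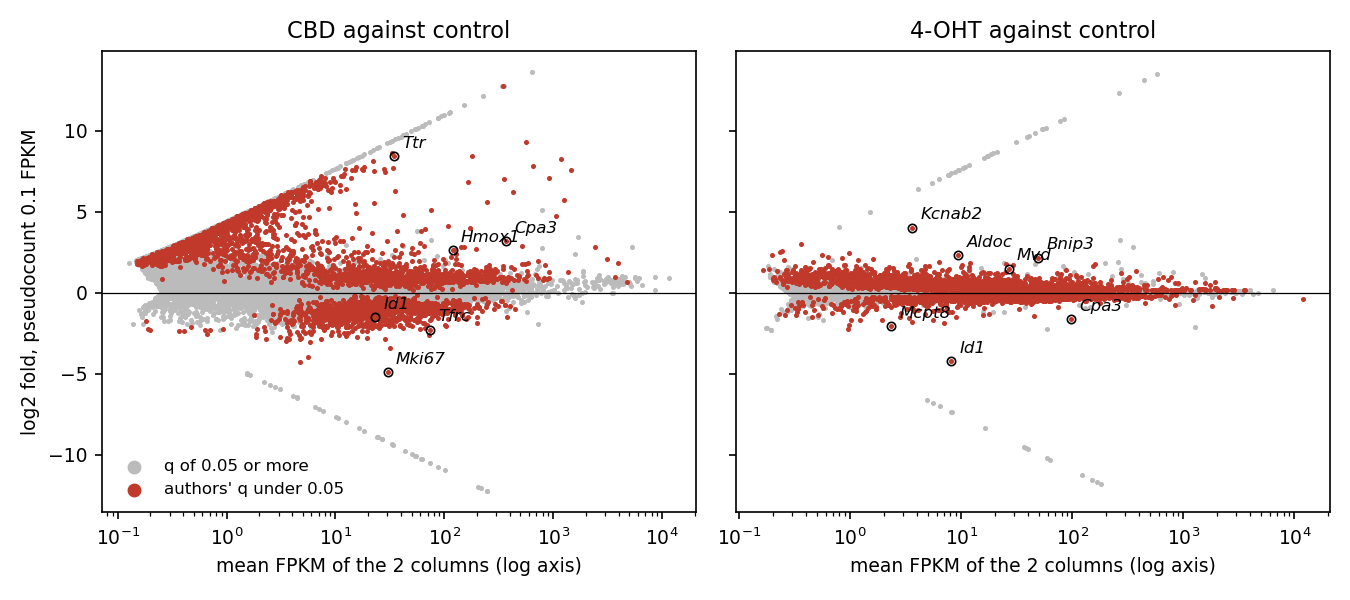
Each point is a tested gene, placed by the mean FPKM of control and treated columns (log axis) and by its log2 fold with a pseudocount of 0.1 FPKM, in red where the authors' q is under 0.05 (CBD left, 4-OHT right). Straight diagonals are genes listed at 0 in 1 column, and called genes spread far wider with CBD, where 2632 differ by at least 2-fold, than with 4-OHT, where 297 do.

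The 4-OHT comparison asks what followed induction of Cre for 48 h in cells with loxP-flanked Id1. Besides Id1, genes of glycolysis and of cholesterol synthesis moved together. Of 30 tested glycolysis and hypoxia genes, 28 rose and none fell, with the same counts adjusted over the list alone. The aldolase gene Aldoc rose from 3.07 to 15.8 FPKM, Bnip3, a mitochondrial protein induced by hypoxia, from 17.8 to 80.6, and Ankrd37 from 4.13 to 11.5. Of 25 cholesterol synthesis genes, 23 rose and 1 fell, again the same adjusted over the list alone. Mvd, the mevalonate pathway decarboxylase, rose from 14.0 to 39.5 FPKM, the sterol reductase gene Tm7sf2 from 2.49 to 6.96, and the sterol oxidase gene Sc4mol from 48.8 to 128. The medians were log2 folds of 0.85 and 0.86, above all 10000 random lists. Against the control column of the other table, 23 of the 28 and 21 of the 23 genes that rose were still higher with 4-OHT, and Aldoc (43.2 FPKM there) and Tm7sf2 (8.005 FPKM there) were not.

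LXR target and cholesterol efflux genes rose in 8 of 9 cases (9 adjusted over the list alone), including the desaturase genes Scd1, from 44.0 to 100.9 FPKM, and Scd2, from 168 to 384, but only 3 of the 8 also exceed the other control column. Of 30 tested G2/M genes, 18 rose and 1 fell (18 and 2 adjusted over the list alone), by small amounts: Nusap1, a spindle protein, from 30.6 to 42.7 FPKM and cyclin B2 (Ccnb2) from 75.03 to 101.8. The list's median log2 fold was 0.20, and 17 of the 18 lie above the other control column as well. MYC target and ribosome biogenesis genes fell in 20 of 30 cases and rose in 2 (22 and 3 adjusted over the list alone), with Rrp12, a ribosome maturation factor, from 53.01 to 35.9 FPKM. Only 5 of these 20 lie below the other control column.

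Immediate early, NF-kB and FoxO target genes rose with 4-OHT against its own control and not against the other. Of 21 immediate early genes 15 rose and 1 fell (16 and 1 adjusted over the list alone), with Egr1 from 2.26 to 7.26 FPKM and Fos, an AP-1 subunit, from 0.151 to 0.641. Of 15 NF-kB genes 13 rose and none fell, the same adjusted over the list alone, with the cytokine gene Tnf from 0.887 to 2.21 FPKM. Of 18 FoxO target genes 12 rose and 1 fell, the same adjusted over the list alone, with Ccng2, cyclin G2, from 5.19 to 18.9 FPKM and Cdkn1b, the CDK inhibitor p27, from 12.1 to 23.0. In the separately made CBD table the control column holds 57.6 FPKM of Egr1, so 4-OHT lies below it. The numbers of these genes that rose and also exceed the other control column are 1 of 15, 4 of 13 and 2 of 12.

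NRF2 and oxidative stress genes fell in 13 of 25 cases with 4-OHT and rose in 5 (14 and 5 adjusted over the list alone), among them the quinone reductase gene Nqo1, from 44.4 to 22.4 FPKM, and the ferritin light chain gene Ftl1, from 2319 to 1321. Of the 13, 4 lie below the other control column, and Nqo1 and Ftl1, at 17.6 and 1295 FPKM there, are not among them. In the BCL2 family list 14 of 22 genes rose and 2 fell, the same adjusted over the list alone, with the BH3-only gene Bmf from 0.620 to 1.52 FPKM. Of those 14, 6 exceed the other control column, against which the list median was 0.043, and Bmf, at 2.64 FPKM there, does not. Mast cell genes split, 7 rising and 6 falling of 17 (8 and 6 adjusted over the list alone): the protease genes Mcpt8, from 3.80 to 0.842 FPKM, Cpa3, from 148 to 48.2, and Tpsb2, from 4.24 to 1.41, fell. Mcpt1, a further mast cell protease gene, fell from 11.1 to 2.94 FPKM. The other control column holds 1.57 FPKM of Mcpt1 and 1.40 of Tpsb2, so neither lies below it. Ly6a, the stem cell antigen Sca-1, fell from 5.65 to 1.55 FPKM, and Meis1, a homeobox gene of leukemic self-renewal, rose from 0.591 to 2.14, although the other control column holds 5.19.

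The highest fold with 4-OHT belonged to Kcnab2, a potassium channel subunit, from 0.333 to 6.90 FPKM, yet the control column of the CBD table lists it at 50.4. Further genes at the top were the muscle filament gene Des, from 0.552 to 2.67 FPKM, the LIM protein gene Csrp2, from 0.405 to 1.956, and the nuclear long noncoding RNA Neat1, from 2.63 to 9.94. Des and Csrp2, at 11.1 and 2.21 FPKM in the other control column, do not exceed it. Sap25, from 1.45 to 5.28 FPKM, overlaps an annotated readthrough transcript and is uncertain. After Id1, Mcpt8, Mcpt1 and Ly6a, the lowest folds were those of the glutathione transferase gene Gsta3, from 1.61 to 0.428 FPKM, the kinase gene Stk32a, from 3.03 to 0.868, the cytochrome oxidase subunit gene Cox6a2, from 1.93 to 0.531, and the actin-severing protein gene Scin, from 8.58 to 2.61. Stk32a is at 0.473 FPKM in the other control column and so does not lie below it.

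In all, 4951 of 11232 tested genes differed with 4-OHT, 3055 higher and 1896 lower. Most changes were small: the median absolute log2 fold of called genes was 0.31 with 4-OHT and 1.71 with CBD, and 297 genes differed by at least 2-fold. The 2 tests call folds of one size unequally often. Among genes at 10 FPKM or more in both columns with an absolute log2 fold of 0.5 to 1, 45.1% were called with CBD and 91.5% with 4-OHT. Numbers of called genes, and medians over them, are therefore not comparable between CBD and 4-OHT. Over all tested genes at 10 FPKM or more in both columns, the SD of the log2 fold was 0.67 with CBD and 0.27 with 4-OHT. Of the 3055 genes that rose, 1564 (51.2%) exceed the control column of the other table. Of the 1896 that fell, 662 (34.9%) lie below it. With CBD these shares were 98.5% and 93.3%. However, 1210 of the 2533 genes that rose with CBD stood under 0.1 FPKM in its control. A gene that is low in both control columns exceeds either almost by construction.

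**Figure D3:**
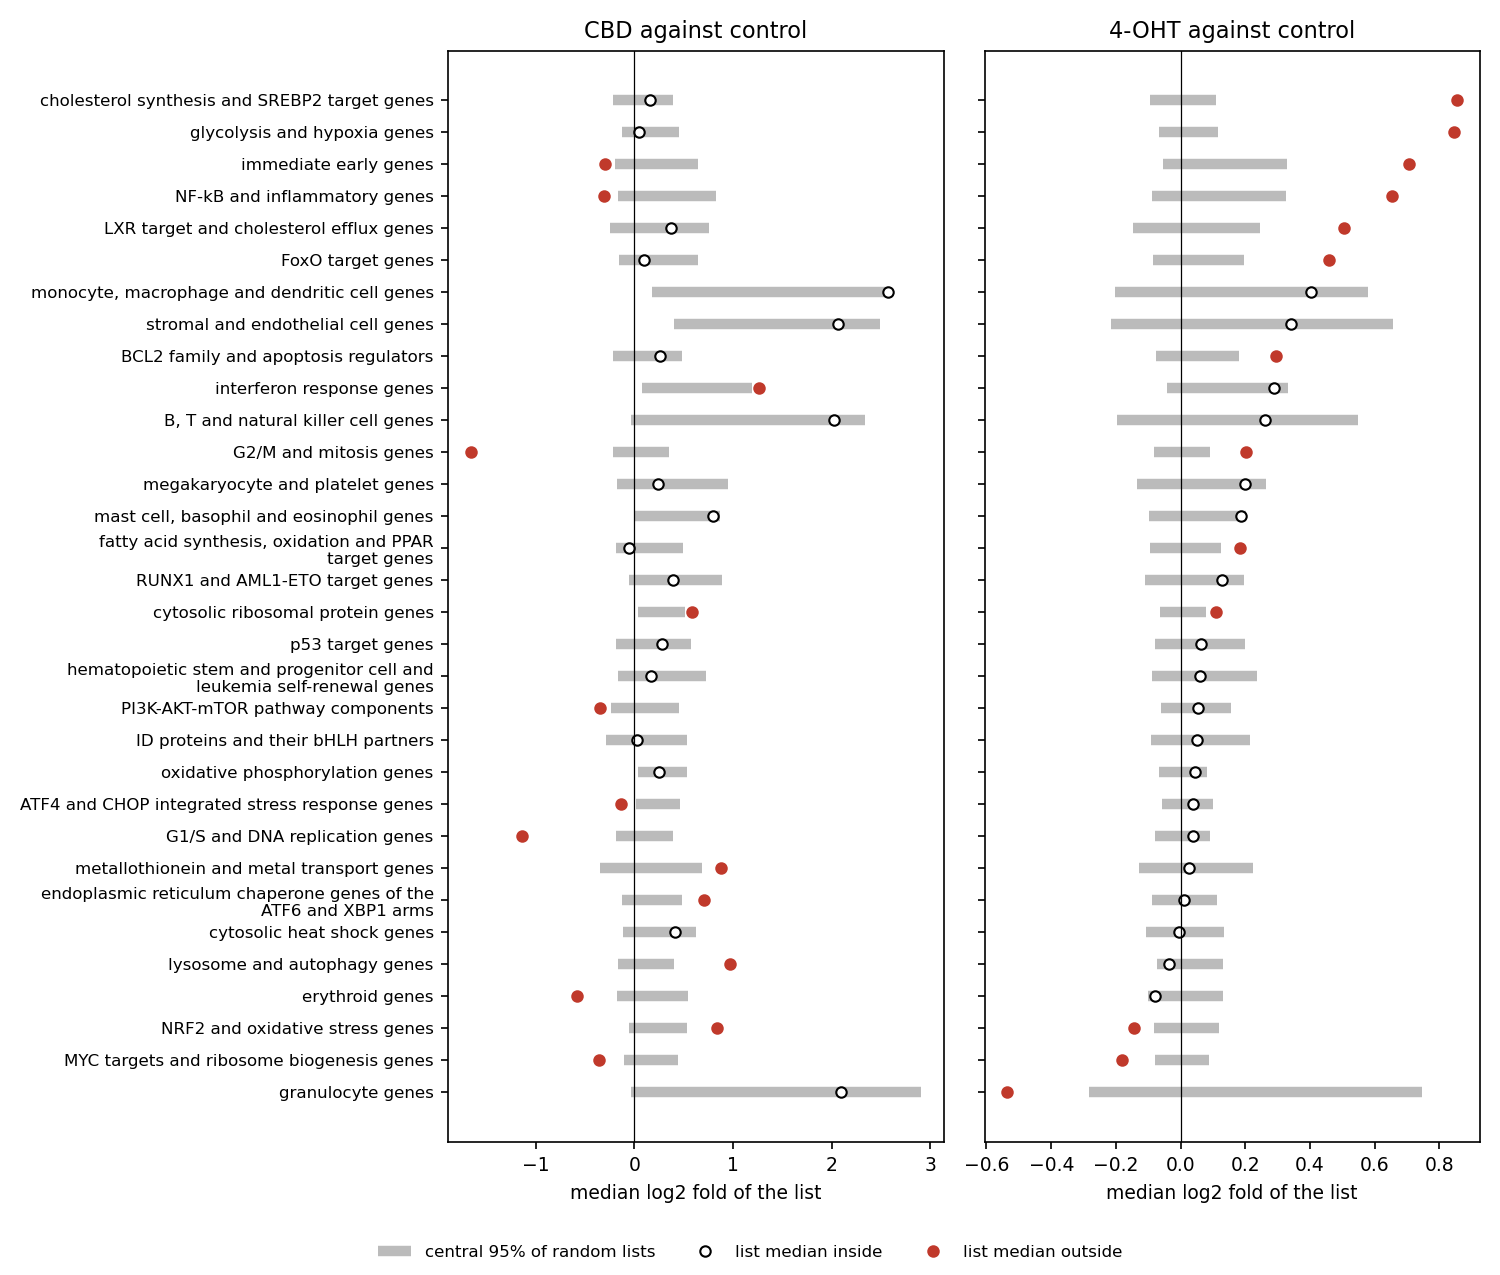
Points give the median log2 fold of each of 32 gene lists fixed in advance, for CBD (left) and 4-OHT (right), on horizontal axes of different scale, with grey bars for the central 95% of 10000 random lists matched on size and expression. Red points lie outside, 14 lists with CBD and 13 with 4-OHT. If genes of a list moved independently, 1.6 would lie there, but they move together, so these counts are no test.

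The remaining lists outside the central 95% had few called members or small medians. With CBD these were PI3K-AKT-mTOR components (median −0.35, 2 higher and 3 lower of 24, Mtor falling from 11.3 to 6.10 FPKM, a log2 fold of −0.88 that became −0.14 with the length trend removed), ATF4 and CHOP genes (median −0.14, 3 and 5 of 42), NF-kB genes (median −0.31, 0 and 1 of 21) and immediate early genes (median −0.30, 1 and 2 of 23). With the length trend removed, the PI3K-AKT-mTOR, NF-kB and metal transport lists no longer lay outside, and against the other table's control the ATF4, NF-kB and immediate early lists had positive medians. The metallothionein and metal transport list had a median of 0.87 with 2 higher and 1 lower of 11. Adjusted over the list alone, the counts of these 5 lists were 1 and 3, 2 and 4, 0 and 1, 1 and 2, and 2 and 1. With 4-OHT the fatty acid list had 10 higher and 4 lower of 20 (median 0.18, the same counts adjusted over the list alone), of which 5 and 1 keep that side of the other control column, and the ribosomal protein list 13 higher and none lower of 34 (median 0.11), where 11 rose adjusted over the list alone. Of those 13, 1 exceeds the other control column, against which the ribosomal protein median was −0.21. Granulocyte genes had 2 lower of 4 (median −0.54, also 2 adjusted over the list alone), namely Gfi1, from 0.598 to 0.308 FPKM, and Cxcr2, from 4.67 to 3.78. Against the other control column the granulocyte median was 0.43, and Cxcr2, at 1.88 FPKM there, is not below it.

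Because both treatments are directed at Id1, their responses were set side by side over the 10867 genes tested in both tables. In the same direction, 367 genes rose and 235 fell in both, against 324 and 180 for independent lists of these sizes. In opposite directions, 205 rose with CBD and fell with 4-OHT, and 363 did the reverse, against 201.3 and 289.8. Genes that rose in both included Scpep1, a serine carboxypeptidase, Mt3, Ypel3, the interferon regulatory factor gene Irf7 (1.87 to 7.89 FPKM with CBD and 0.891 to 2.14 with 4-OHT) and Tnfaip8l2. Of these 5, Irf7 alone also exceeds with 4-OHT the control column of the CBD table. Mcpt8, Ly6a, Cox6a2 and Scin rose with CBD and fell with 4-OHT, Scin from 8.17 to 125 FPKM and from 8.58 to 2.61, while Egr1 went the other way. Across 9804 genes at 1 FPKM or more in both tables, the fold changes had a Pearson r of −0.075 and a Spearman rho of 0.008. Genes are not independent replicates. Whether the 2 control columns share libraries is not stated, so the overlap that shared controls alone would give could not be simulated. With 2 control samples in all, a column pooling both could hardly lie far more than 2-fold below the other. In the CBD table's control, Slc40a1 (5.56 against 22.6 FPKM) and Hsph1 (40.7 against 152.6) lie that far below. In the 4-OHT table's control, Nupr1 (12.5 against 159.9) and Trib3 (32.5 against 260.2) do. These genes, chosen after their values were seen, argue against shared control libraries.

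The 2 control columns, both named as control and made separately, differ from each other. Over 6102 genes at 10 FPKM or more in both, the SD of their log2 ratio was 0.51. It was 0.34 for 4-OHT and 0.90 for CBD, each over its own control. At least 2-fold differences between the control columns were found in 299 of these genes, against 54 with 4-OHT and 860 with CBD. Over list members at 1 FPKM or more in either control column, the control of the CBD table was higher by a median log2 of 2.26 for 18 immediate early genes, 1.60 for 4 stromal genes, 1.002 for 17 NF-kB genes and 0.89 for 41 ATF4 and CHOP genes. Among single genes, chosen after their values were seen, were Trib3 at 260.2 against 32.5 FPKM, Ddit3, which encodes CHOP, at 191 against 26.9, Nupr1 at 159.9 against 12.5, and Ddit4 at 113.0 against 13.4.

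**Figure D4:**
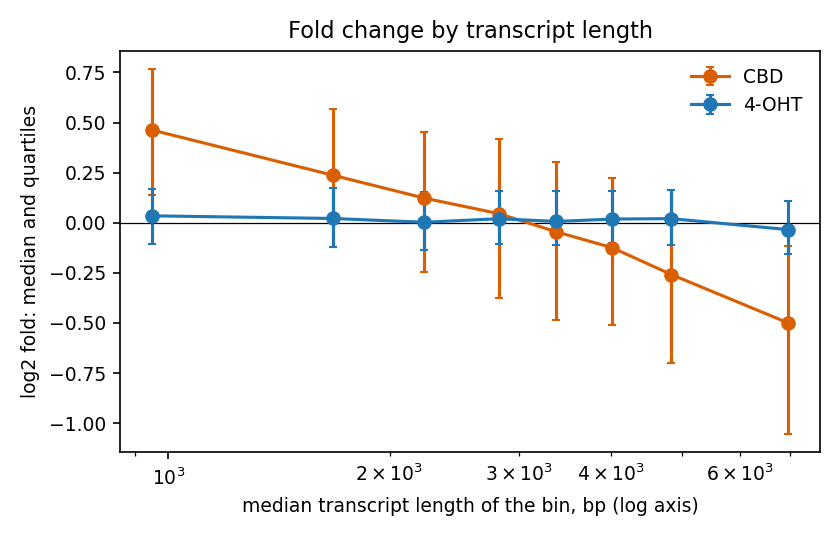
Points are the median log2 fold of 754 or 755 genes per bin of transcript length (log axis), with bars from the lower to the upper quartile. With CBD the median goes from 0.46 in the shortest bin to −0.50 in the longest, and with 4-OHT it stays between −0.03 and 0.03.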

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

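Of the tests in this part, the adjustment for transcript length alone was chosen before its result was seen, and the others were chosen afterwards.

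Transcripts of neurons, oligodendrocytes and astrocytes, which no comparison of the study concerns, reached a median of 9.53 FPKM in the CBD column, against 0.0354 in its control and 0.0119 and 0.0123 in the control and treated columns of the 4-OHT table. The summed FPKM of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty was 1.97 in the CBD column and 0.0393 in its control. Between the control columns, which carry the same name, 299 genes at 10 FPKM or more differ by at least 2-fold.

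The first pattern is the neural and Y-linked signal of the CBD column. The neuropeptide gene Penk stood at 28.2 FPKM with CBD, and Mbp, myelin basic protein, at 118 against 38.6 in its control. Of the 55 neural genes 5 are at 1 FPKM or more in the control, 2 also belong to fixed lists, and 49 rose. A rise of silent genes in general, as genomic DNA would give, is argued against by 96 genes of 7 other tissues, whose median was 0.0348 FPKM. Induction of Y-linked genes in the leukemia cells is argued against by the controls, where Xist, expressed from an inactive X chromosome, stands at 9.46 and 19.0 FPKM and the Y-linked sum is at most 0.415% of it. In the CBD column Xist is lower, at 2.84 FPKM beside the Y-linked 1.97, and it is at 33.5 FPKM with 4-OHT. No single Y-linked gene reaches 1 FPKM in the CBD column.

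What stays open for this pattern is RNA from nervous tissue of a male animal in the CBD libraries, for which the lowest of the 3 neural list medians, 4.76 on the log2 scale, and the higher values of all 4 Y-linked genes (3 were tested and rose, Kdm5d was not tested) are what it needs. Reads of another library mixed in may give the same values. Induction of the 49 neural genes by CBD in the leukemia cells would not by itself raise the Y-linked genes, of which the 3 tested rose. With both raised, RNA of another animal gives the same neural values, so induction of the neural genes cannot be told apart from it. Of 9254 genes under 0.1 FPKM in the other 3 columns, 1109 are at 1 FPKM or more with CBD, and the 9254 together carry 1.08% of its summed FPKM.

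The second pattern is the fall of cell cycle genes with CBD. The trend with transcript length is argued against as the whole cause: over 57 G1/S and G2/M genes the median log2 fold was −1.36 before and −1.38 after its removal, with quartiles of −1.76 and −1.09, below all 10000 random lists. Dilution of leukemia RNA by RNA of non-dividing tissue was tested first by medians. The difference was 1.19 between 39 blood lineage genes (−0.16) and 53 cell cycle genes (−1.36), all at 10 FPKM or more in both control columns. It was within the quartile range of 1.38 of the lineage genes, which was called undecided. That range is a spread of single genes and no uncertainty of a median, so this comparison could not decide. A second test, chosen after that result, counted lineage genes at or below the median of those 53: 5 of 39, or 12.8% (exact binomial 95% interval 4.30% to 27.4%), where dilution needs about 50% or more. The lineage median already lay above −1.36, so a share under 50% was fixed before this count, which is no separate evidence. Of the 39 lineage genes, 10 rose and 7 fell. Over all tested genes at 10 FPKM or more in both control columns the median log2 fold was 0.007. These values show that lineage genes fell less than cell cycle genes at the median, and the extent of any dilution was not measured. An effect of CBD on the leukemia cells stays open and was not tested, and other technical causes were not excluded.

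The third pattern is that the direction of several lists with 4-OHT depends on which control column is used. The source of the difference between the control columns was not tested. For glycolysis and cholesterol synthesis that difference is argued against as the whole cause. Their medians against the other control were 0.50 and 0.62, with a lowest percentile of 100 among random lists. This covers the 2 control columns alone, and a culture difference of the 4-OHT samples from both was not tested. For immediate early, NF-kB and FoxO genes the difference between the control columns may be the cause. Over their 21, 15 and 18 tested members, it has medians of 2.03, 0.79 and 0.73. The 4-OHT medians against the other control were −1.60, −0.39 and −0.35, at percentiles of at most 0.6. Both sets of values use the same control columns, so they are not separate evidence. Loss of Id1 stays open for all 5 lists and was not tested, as no 4-OHT arm without loxP sites is in the labels.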

How the results depend on the processing

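Alternatives named here as chosen after the data were seen are the minimum of 1 FPKM in both control columns, the control column of the other table, the removal of the length trend and, for named genes, the pseudocounts, and the rest were set beforehand. No paired analysis was possible because the tables give 1 value per group and no library can be matched to another. Leaving out single libraries, a replicate block, and a count model with other size factors or no count filter were not run, since neither libraries nor counts are in these tables, and no symbol is repeated. Depth is unknown, so what it limits cannot be stated.

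The count of genes changed with CBD was 3598. It was 2023 with a pseudocount of 1 and a minimum of 2-fold, 2044 among genes at 1 FPKM or more in both control columns, and 2398 at 2-fold with the length trend removed. The limits of 2-fold and of 1 FPKM leave fewer genes by construction. The 2-fold limit alone gave 2632, and the pseudocount of 1 and the removal of the length trend also changed the folds. Under the other 7 alternatives the count of genes changed with CBD stayed within 1.5 times, from 2562 to 3488. The 4951 genes changed with 4-OHT became 297 at 2-fold, 276 at 2-fold with folds centred, 366 and 74 at 2-fold with pseudocounts of 0.01 and 1, 290 at 2-fold with the length trend removed, and 2226 when the gene had to lie on the same side of the other control column. Under the other 4 alternatives it lay between 3739 and 4819. Centring moved log2 folds by 0.19 with CBD and 0.04 with 4-OHT.

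Id1 kept its direction under all 4 alternatives in both comparisons. Against the other control column its log2 fold was −0.37 with CBD and −5.35 with 4-OHT, and the cause was not tested. The number of CBD lists outside the central 95% went from 14 to 9 with the length trend removed and lay between 12 and 16 under the other 6 alternatives, and for 4-OHT it was 13 or 14 under all 7. The 602 genes changed in the same direction in both became 328 at a q of 0.01 and 25 at 2-fold in both, by the stricter limits. The correlation of the comparisons, −0.075, was −0.10 over genes at 10 FPKM or more, and the cause was not tested.

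Of 224 list medians recomputed for CBD, 190 kept their direction and side of the limits, 11 moved outside, 16 moved inside, 4 that had lain inside changed sign and 3 that had lain outside reversed. Of 223 for 4-OHT these numbers were 193, 5, 4, 13 and 8. All reversals came from the control column of the other table, and the cause was not tested. With CBD the reversed medians were ATF4 and CHOP 0.99, NF-kB 1.26 and immediate early 1.70. With 4-OHT they were FoxO −0.35, LXR −0.23, NRF2 0.068, ribosome biogenesis 0.24, NF-kB −0.39, immediate early −1.60, granulocyte 0.43 and ribosomal protein −0.21.

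Of the values of named genes, 3 of 332 with CBD and 53 of 387 with 4-OHT changed direction, all against the other control column, where a further 80 and 44 were recomputed without a test and kept their direction. Under the pseudocounts and the length trend all 249 and 290 kept theirs. The cause was not tested. The reversed log2 folds with CBD were Egr1 1.19, Nupr1 2.55 and Ier2 1.35. With 4-OHT, genes that had fallen were higher than the other control column: Id2 0.85, Mcpt1 0.86, Stk32a 0.76, Ccne1 0.76, Pola1 0.43, Canx 0.46, Nqo1 0.35, Ftl1 0.029, Slc40a1 0.60, Cad 0.37, Odc1 0.76, Cycs 0.54, Cxcr2 0.97, Rhag 1.27 and Tpsb2 0.0098. Genes that had risen were lower than it: Kcnab2 −2.85, Aldoc −1.44, Des −2.01, Csrp2 −0.17, Ccng2 −0.083, Cdkn1b −0.16, Cdkn1a −0.94, Ddit4 −1.33, Pik3ip1 −1.20, Bok −1.70, Bmf −0.76, Atf3 −2.41, Nupr1 −2.42, Xbp1 −0.18, Herpud1 −1.51, Tm7sf2 −0.20, Elovl5 −0.045, Mt3 −0.82, Mt1 −0.068, Tnf −1.65, Cxcl2 −1.24, Relb −1.23, Egr1 −2.97, Fos −3.77, Meis1 −1.24, Fli1 −0.16, Lat −1.65, Nkg7 −0.33, Sparc −0.41, Vim −0.95, Map1lc3a −0.34, Hexa −1.85, Rpl13a −0.51, Rpl10a −0.36, Rpl3 −0.21, Scpep1 −1.59, Ypel3 −0.66 and Tnfaip8l2 −2.39.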

Other observations

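The values in this part were picked after they were seen, apart from the list counts, which follow the fixed lists. RUNX1, the protein that the AML1-ETO fusion is made from, has its gene Runx1 falling with CBD from 92.6 to 47.4 FPKM, with Runx3 from 16.5 to 6.90 and Runx1t1, the gene of the fusion partner, from 6.95 to 2.81. In the list of RUNX1 and AML1-ETO target genes 5 of 21 rose and 5 fell with CBD (7 and 5 adjusted over the list alone), and 7 of 14 rose and 3 fell with 4-OHT (7 and 3). Plac8, a myeloid gene, and Gzmb rose with CBD, Plac8 from 41.6 to 189 FPKM, and both fell with 4-OHT, Plac8 from 18.02 to 11.04 and Gzmb from 25.3 to 10.05. The cell cycle inhibitor gene Cdkn2a rose with CBD from 222.6 to 429.7 FPKM. In the stem and progenitor list 3 of 20 rose and 1 fell with CBD (3 and 1 adjusted over the list alone) and 6 of 19 rose and 6 fell with 4-OHT (6 and 6), where the receptor gene Kit fell from 95.6 to 78.8 FPKM, Myb from 112.0 to 97.7, and Hoxb4 rose from 0.251 to 0.579.

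Further fixed lists stayed inside the central 95% of random lists. With CBD these were, as genes higher and lower of those tested, ID proteins and partners 5 and 3 of 16, FoxO targets 3 and 1 of 22, p53 targets 6 and 2 of 24, BCL2 family 1 and 0 of 24, heat shock 2 and 1 of 18, cholesterol synthesis 1 and 0 of 25, LXR 3 and 4 of 12, fatty acid 5 and 2 of 23, glycolysis 2 and 3 of 29, oxidative phosphorylation 2 and 0 of 30, granulocyte 2 and 0 of 7, and megakaryocyte 3 and 1 of 12. With 4-OHT they were ID proteins and partners 6 and 4 of 16, PI3K-AKT-mTOR 9 and 1 of 26, G1/S 6 and 2 of 30, p53 targets 10 and 4 of 21, ATF4 and CHOP 17 and 9 of 41, endoplasmic reticulum chaperones 6 and 7 of 25, heat shock 1 and 2 of 16, metal transport 4 and 5 of 11, oxidative phosphorylation 7 and 3 of 31, interferon 11 and 2 of 23, monocyte 2 and 1 of 6, erythroid 1 and 8 of 19, megakaryocyte 4 and 2 of 12, lymphoid 2 and 0 of 6, stromal 2 and 0 of 7, and lysosome 7 and 7 of 28.

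Of the lists written after the data were seen, the neuron list had 22 of 23 tested genes higher with CBD, the oligodendrocyte list 13 of 16, the astrocyte list 14 of 16 and the microglia list 4 of 12, with none lower, and all 3 tested Y-linked genes rose. Over all their members, the median log2 fold with CBD was 0.17 for liver genes, 0.28 for muscle, 0.21 for kidney and 0.25 for skin, and it was 0 for testis, lung and gut. With 4-OHT, 2 of 7 tested astrocyte genes rose and 1 fell, 1 of 3 microglia genes rose, neither of 2 neuron genes passed the test, and 1 of 2 oligodendrocyte genes fell, namely Mbp, from 32.0 to 28.6 FPKM.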
